A study of Mus musculus with 97 samples.

How the data were processed

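RNA from liver and kidney was measured by sequencing with a stranded total RNA kit, per the labels. The labels list 97 samples, 49 of liver and 48 of kidney, and the count tables gave 94 libraries; 3 liver samples, numbers 4, 20 and 22, were not analysed here. Values in both tables are raw counts per gene, made by the authors with STAR against mm10 or GRCm38.p6, per the deposited processing notes, which state no version. The program that counted the reads, its annotation and its strand setting are not given in the sources used here. The deposited counts in the liver table cover 38924 gene identifiers, of which 37607 matched the reference annotation (the other 1317 held 0.0974% of the counts). The kidney table covers 19838 gene symbols, of which 19590 matched (the other 248 held 0.482%), and it holds autosomal protein-coding genes only. The rows N_ambiguous, N_multimapping and N_noFeature stayed out of library sizes and tests; as a share of gene counts plus these tallies they came to 4.61 to 6.10%, 5.60 to 11.0% and 2.77 to 5.83% in the liver and 0.732 to 1.52%, 1.94 to 3.96% and 15.3 to 31.4% in the kidney.

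Libraries were grouped by treatment, sex and age class as the labels give them, 12 groups per tissue. The age classes, 2 months, 20.5 to 22 months and 27.6 to 29.2 months, are a grouping made here. The labels give no batch, date or litter. They number the libraries, with the same numbers in both tissues, without stating that a number is 1 mouse, so p values measure the spread between these libraries.

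Each tissue was fitted with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr with a minimum count of 10 and a minimum total of 15, robust quasi-likelihood F tests) on the 12 groups. This tested 15486 genes in the liver and 14979 in the kidney, with a common biological coefficient of variation of 0.377 and 0.383. Genes with a Benjamini-Hochberg adjusted p under 0.05 within a comparison are called. Comparisons were rapamycin against control at each age class in the mean of both sexes and in each sex, the interactions of rapamycin with sex and with age, ageing in controls (28 against 2 months) and sex in controls (male against female). Fold changes are log2 with a prior count of 0.125, standard errors come from the fitted model, and group levels are CPM with TMM factors. The tissues were compared in a joint fit of 24 groups over the shared genes. Gene lists fixed before the tests, with at least 5 members tested, were tested with fry of limma 3.58.1 and again with camera, with an estimated and with a preset correlation of 0.01.

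For the ageing score, genes came from the controls of the other sex, 53 that rose and 17 that fell for male livers, 75 and 41 for female livers, 10 and 1 for male kidneys and 313 and 57 for female kidneys. Scores were compared by exact permutation of treatment within each sex. Alternatives were DESeq2 1.42.0 (Wald tests, and likelihood ratio tests for interactions with several terms), RLE size factors, no expression filter, age in months as a covariate, fits of fewer groups, limma voom for the joint fit, a block on the shared number in edgeR (a coefficient for each number that has both tissues), other definitions of ageing, and leaving out each library in turn. After the data had been seen, fits without kidney 35, without kidneys 6 to 11 and without both, with kidneys 11 and 12 summed, and with a fat covariate were added.

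Genes named in the text followed a rule fixed in advance: an assigned symbol and a mean of at least 1 log2 CPM. For rapamycin in both sexes these were up to 12 called genes each way with the largest fold, or the 5 with the smallest p where fewer passed. In a single sex up to 5 each way were named, or 3 by p where none passed. For interactions and the tissue difference up to 8 by p were named, for ageing and sex up to 10 each way by fold, with the sex-linked Xist, Ddx3y, Eif2s3y, Kdm5d and Uty always, and 2 to 4 members of each list described by p.

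The pipeline was tested on simulated data with 200 changed genes among 15182 in the liver and 14836 in the kidney. In both sexes together it recovered 24, 78, 96 and 90% of genes changed 1.5-fold, 2-fold, 3-fold and 4-fold in the liver and 34, 62, 88 and 94% in the kidney. In females alone it recovered 40% of genes changed 2-fold in either tissue, so smaller changes in a single sex are mostly missed. In the simulated comparison without changes no gene was called by edgeR, and 1 list was called in each tissue. At 2 months 6 of 150 liver calls and 10 of 149 kidney calls were false in both sexes together. The false calls were 11 of 132 and 2 of 114 in males, and 4 of 115 and 2 of 101 in females. All changed genes had a mean of at least 1 log2 CPM, so recovery of lower genes was not tested. Kidneys 11 and 12 were the closest pair within a group, at 5.37 chi-square per degree of freedom against 15.8 for the next of 77 pairs, and were kept as 2 libraries.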

Results

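The series measured gene expression in liver and kidney of UM-HET3 mice, a genetically heterogeneous cross-bred stock in which every animal carries its own mix of parental genomes. Pups received a diet with encapsulated rapamycin, an inhibitor of the growth-controlling kinase mTORC1, or with the encapsulating material alone (Eudragit, the control) starting at birth and ending at 45 days. Tissues came from 3 age classes, 2 months, 20.5 to 22 months (here the 22-month class) and 27.6 to 29.2 months (the 28-month class), and from both sexes, so each tissue had 12 groups. The count tables gave 46 liver and 48 kidney libraries. At 2 months there were 3 control and 4 rapamycin males and 3 control and 3 rapamycin females in each tissue. At 22 months there were 4 and 4 males and 5 and 4 females, with 3 rapamycin females in the liver. At 28 months there were 3 and 5 males and 6 and 4 females, with 2 control males in the liver. Library totals ran from 12.7 M to 52.8 M gene counts in the liver (median 17.4, second highest 24.7) and from 12.9 to 22.0 M in the kidney (median 17.2). The comparisons below ask what rapamycin in early life changed shortly after treatment ended, whether anything remained in old age, and how both compare with ageing and with sex.

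Sex-linked transcripts matched the sex label in all 46 livers. Xist, the RNA that silences the second X chromosome, was between 255 and 586 CPM (counts scaled to the library total) in female livers and at most 1.35 in male livers. Ddx3y, a Y-linked RNA helicase gene, was between 23.6 and 67.1 CPM in males and at most 0.816 in females. The kidney table held only autosomal protein-coding genes, so the same check could not be run there. Several kidneys stood apart. The 28-month male rapamycin kidney of number 35 held 51947 CPM of Scgb1a1 and 17499 CPM of Sftpc, secreted products of lung airway and alveolar cells, against at most 0.169 and 0.391 CPM in the other 22 male kidneys. Its Umod, a protein of the thick ascending limb, was at 21.1 CPM against 1176 to 7188 CPM, and its Kap, an androgen-regulated kidney gene, at 125 CPM against 5920 to 34195 CPM. The kidneys numbered 6 to 11 resembled the liver of the next number more than the liver of their own number. Over the 100 genes that best tied liver to kidney in numbers 13 to 49, their correlation across genes was 0.56 to 0.76 with the next liver and -0.06 to 0.53 with their own. Of 6 other kidneys that had no part in choosing these genes, 5 correlated best with their own liver. All labels were kept as given, and the kidney counts below were repeated without these libraries.

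**Figure D1:**
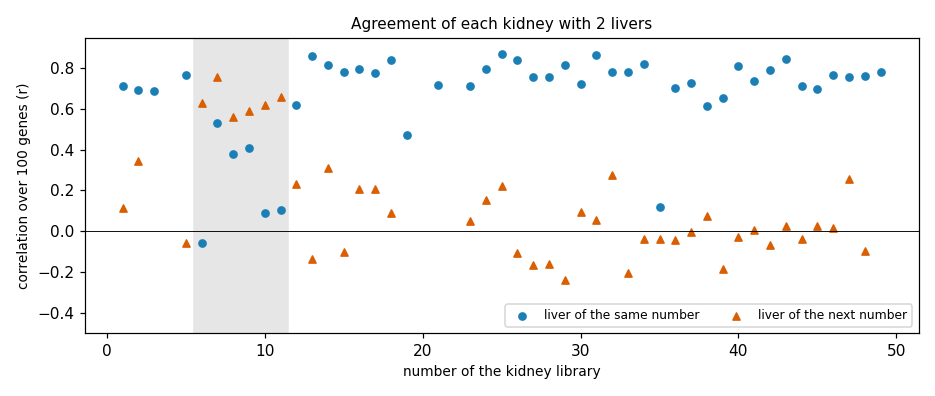
Correlation across 100 genes (vertical axis, r) of each kidney library (horizontal axis, its number) with the liver of the same number (circles) and of the next number (triangles). In the shaded range, numbers 6 to 11, all 6 triangles lie above the circles, with r of 0.56 to 0.76.

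In the liver at 2 months, soon after the diet had ended, 15 of 15486 genes differed between rapamycin and control when both sexes were averaged, 1 higher and 14 lower. Zap70, the kinase that relays the T cell receptor signal, fell by 1.64 ± 0.25 (log2, SE; edgeR adjusted p = 0.00146), from 8.19 ± 1.53 to 2.73 ± 0.97 CPM in males (SD, n = 3 and 4). In females it went from 12.6 ± 4.83 to 3.8 ± 0.559 CPM (n = 3 and 3). Slc3a1, a subunit of the transporter for cystine and dibasic amino acids, fell by 1.41 ± 0.23 (edgeR adjusted p = 0.00191), and Slc43a1, a transporter of large neutral amino acids, by 1.26 ± 0.24. Hspb1, a small heat shock protein, fell by 2.63 ± 0.45 (edgeR adjusted p = 0.00523). Pigr, the receptor that carries IgA into bile, fell by 0.65 ± 0.12, from 1159 ± 132 to 546 ± 134 CPM in males and from 1603 ± 209 to 1384 ± 296 CPM in females. Fitm1, which helps package fat into lipid droplets, was the 1 gene that rose, by 2.05 ± 0.41 on the log2 scale, from 3.83 ± 1.74 to 15.5 ± 6.26 CPM in males. Other named genes that fell were Slc13a2, a citrate transporter (-2.69 ± 0.58), Dpy19l3 (-2.23 ± 0.41) and the interferon-inducible Apol9a (-2.08 ± 0.39). So did Extl1 (-1.91 ± 0.38), the sulfotransferase Sult1c2 (-1.15 ± 0.25) and Sdr9c7 (-0.90 ± 0.20). Grm8, a glutamate receptor, had no counts in any of the 7 rapamycin livers. In males it was at least 14.2-fold lower than the controls' 0.691 CPM, taking a floor of 3 counts over the group. Leaving out any of 7 livers (46, 47, 43, 44, 45, 40 or 37) reduced the count to between 5 and 9 genes, while Zap70, Slc3a1 and Hspb1 passed in all 13 such fits. DESeq2 called 62 genes, including all 15, and a fit of the 4 groups of this age alone called 8, of which 6 were shared.

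Among males alone, 26 liver genes differed at 2 months, 2 higher and 24 lower. Cyp2a22, a cytochrome P450 with close relatives that can share reads, was higher at 24.5 ± 26.4 against 2.55 ± 1.80 CPM (log2 change 3.27 ± 0.71, edgeR adjusted p = 0.0407), and Corin, a protease that activates natriuretic peptide, rose by 1.30 ± 0.28. Slc13a2 fell by 4.12 ± 0.84. Awat2 and Far1, both enzymes of wax ester synthesis, and the stress gene Nupr1 were called lower in males, but 1 control liver, number 41, carried them: without it their log2 changes were 0.98, 0.47 and 0.36. Leaving out 41, 37, 38, 39 or 49 left 10, 12, 15, 11 or 17 genes, and a fit of the 2 male groups alone called 1, which is not among the 26. In females no gene passed with edgeR (435 at an unadjusted p under 0.05, 9 with DESeq2). The smallest p values were for Cyp3a44 (-3.59 ± 0.71), Cyp3a16 (-5.09 ± 1.02), both from a family of near-identical female-biased cytochromes P450 that can share reads, and Zap70 (-1.72 ± 0.37).

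The kidney held more differences at 2 months: 74 of 14979 genes, 15 higher and 59 lower with rapamycin. Uap1l1, related to the enzyme that makes the sugar donor for protein glycosylation, had the smallest p. It fell from 132 ± 10.4 to 36.9 ± 4.79 CPM in males (SD, n = 3 and 4) and from 111 ± 10.3 to 36.2 ± 9.49 CPM in females (n = 3 and 3; log2 change -1.73 ± 0.18, edgeR adjusted p = 1.70e-07). Rnase4 and Ang, ribonuclease genes that share their 5′ exons and promoters on chromosome 14 (51091077 to 51106151, GRCm38.p6), both fell (-3.34 ± 0.48 and -4.0 ± 0.58). Rnase4 went from 65.8 ± 28.7 to 4.20 ± 2.74 CPM in males and from 50.3 ± 3.07 to 7.61 ± 3.74 CPM in females. Because they overlap, reads of Ang can be counted for Rnase4 and the reverse. Nepn, a secreted small leucine-rich protein, fell by 2.65 ± 0.37, from 21.6 ± 0.523 to 1.59 ± 0.51 CPM in males. The glycine cleavage enzyme Gldc (-2.25 ± 0.46), the retinol receptor Stra6 (-2.23 ± 0.46) and the secreted phosphoprotein Spp2 (-2.23 ± 0.39) fell. The transcription factor Etv1 (-2.28 ± 0.38), the adhesion protein Pcdh7 (-2.40 ± 0.39) and the glucuronosyltransferase Ugt2b34 (-2.41 ± 0.39) fell as well. Ugt2b34 has close relatives that can share reads. Cyp27b1, which makes the active form of vitamin D, rose by 2.49 ± 0.61 on the log2 scale (edgeR adjusted p = 0.0479), from 4.83 ± 0.841 to 33.2 ± 11.7 CPM in males and from 4.04 ± 0.736 to 18.6 ± 7.37 CPM in females. Ftcd, an enzyme of histidine breakdown, rose by 2.34 ± 0.51 and Crybg2 by 3.42 ± 0.62. Smaller rises were seen for the AMPK subunit gene Prkag3 (1.93 ± 0.45), the endoribonuclease Endou (1.63 ± 0.28) and Rarres2, the precursor of chemerin (1.32 ± 0.33). The tubulins Tubb4b and Tuba1c rose by 0.56 ± 0.11 and 0.54 ± 0.13.

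Smaller called changes in the 2-month kidney included Pkdcc (0.74 ± 0.15), Spag1 (0.88 ± 0.22), Ubald1 (0.54 ± 0.12) and Sac3d1 (0.51 ± 0.13), all higher. Tmem178b (-2.12 ± 0.43), the lymphoid phosphatase Ptpn22 (-2.93 ± 0.62) and Nlrc5, an activator of MHC class I genes (-2.05 ± 0.48), were lower. Ang, Rnase4, Nepn, Etv1, Spp2, Pcdh7, Ugt2b34, Tmem178b, Crybg2 and Endou passed in all 13 fits that left out 1 of the 2-month kidneys, whereas Cyp27b1 and Rarres2 each lost the call in 12 of them. Leaving out 48, 43, 44 or 41 reduced the count to 47, 32, 41 or 45 genes. Without kidney 35 and its lung transcripts, chosen for removal after the values were seen, the same contrast called 232 genes; without 6 to 11 it called 74, and without all 7 it called 325. DESeq2 called 154, including all 74, and a fit of the 4 groups of this age alone called 403.

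**Figure D2:**
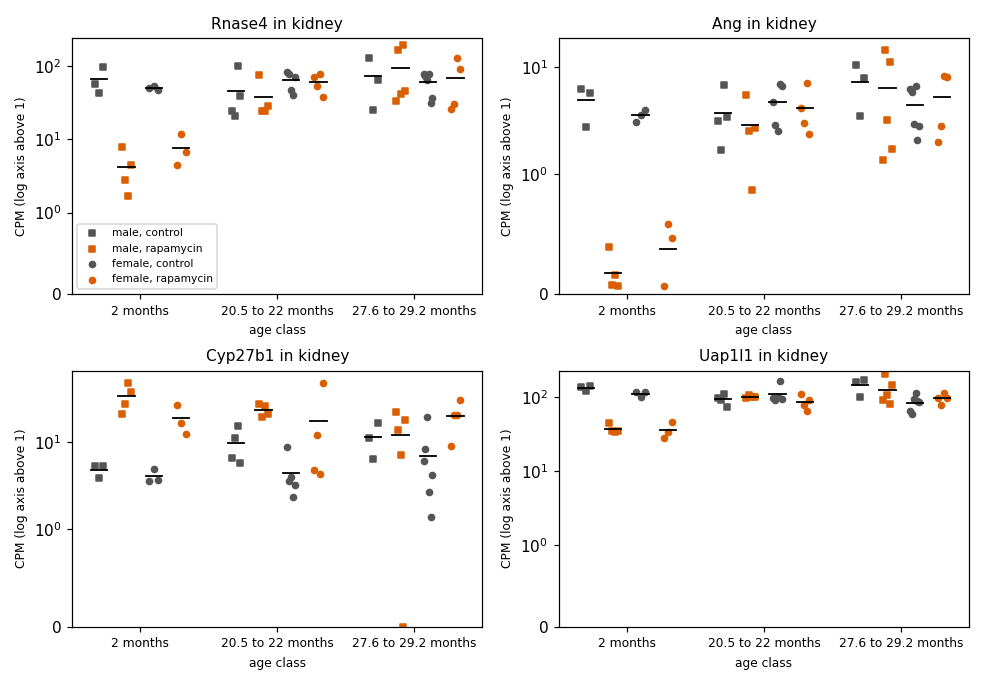
CPM of Rnase4, Ang, Cyp27b1 and Uap1l1 in each kidney (vertical axis, linear below 1 and logarithmic above) by age class (horizontal axis), with squares for males, circles for females, grey for control, orange for rapamycin and a bar at each group mean. At 2 months Uap1l1 means were 132 and 111 CPM in control males and females against 36.9 and 36.2 CPM with rapamycin; the 28-month male rapamycin point without Cyp27b1 counts is kidney 35.

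In male kidneys alone, 104 genes differed at 2 months, 49 higher and 55 lower. Ang (-4.80 ± 0.82), Rnase4 (-3.97 ± 0.66) and Ptpn22 (-4.92 ± 0.89) fell. Ugt2b34 fell as well (-4.21 ± 0.58, from 25.4 ± 3.69 to 1.35 ± 0.823 CPM, n = 3 and 4). The T cell chemoattractant Cxcl9 fell by 5.99 ± 1.43, from 2.80 ± 2.03 to 0.0374 ± 0.0747 CPM. That rapamycin mean lies under the floor of 3 counts over the group, 0.0554 CPM, so the size of the fall is poorly known. Ftcd rose by 2.99 ± 0.73, from 31.6 ± 10 to 251 ± 89.2 CPM, Endou by 2.66 ± 0.41, Igflr1 by 2.06 ± 0.49, Sap25 by 1.82 ± 0.44 and Doc2g by 1.65 ± 0.42. In female kidneys Uap1l1 was the 1 gene called (-1.61 ± 0.27, edgeR adjusted p = 0.00753), and leaving out 46, 48, 43 or 44 ended that call; DESeq2 called 15 genes and a fit of the 2 female groups alone 30. Leaving out 40, 41, 42, 38 or 39 gave 30, 24, 60, 359 or 36 genes in males, and without the kidney of 35 there were 465. A fit of the 2 male groups alone called 91, of which 30 were among the 104. The test of a difference between the sexes in the rapamycin response, over all 3 ages, called no gene in the kidney (786 at an unadjusted p under 0.05, 0 with DESeq2) or in the liver (516, and 2 with DESeq2), so the larger male counts are not shown to differ from the female ones.

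**Figure D3:**
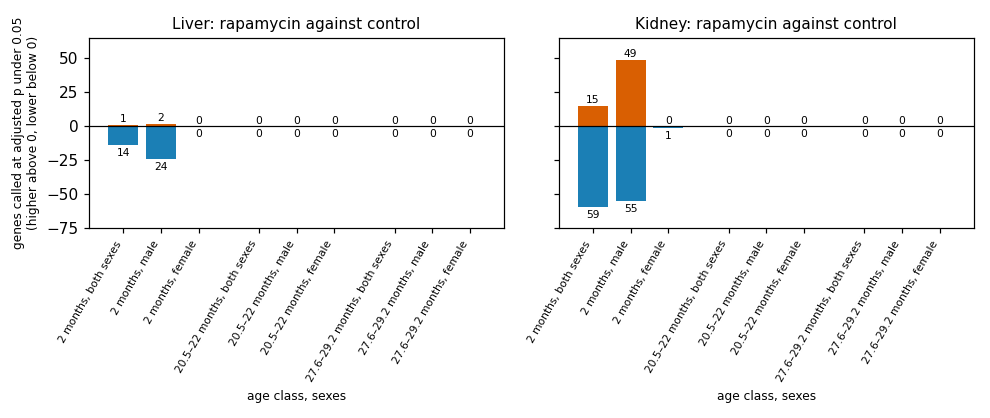
Genes called for rapamycin against control (vertical axis, genes at adjusted p under 0.05; higher above 0, lower below) in liver and kidney by age class and sexes (horizontal axis). At 2 months the bars show 1 higher and 14 lower liver genes and 15 higher and 59 lower kidney genes in both sexes. In males they show 2 and 24 in the liver and 49 and 55 in the kidney. Female kidneys have 1 lower gene, and all bars are at 0 at the later ages.

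Of the gene lists fixed in advance, 44 in the liver and 41 in the kidney were tested for a shared shift by fry, and none passed in any rapamycin comparison. The list closest to the threshold in the 2-month kidney held T and NK cell genes: 28 of 30 members were lower and 1 higher, with a median log2 change of -1.29 (fry adjusted p = 0.0525; adjusted p = 0.33 by camera with an estimated correlation). None of the 30 was called over all genes and 6 were when adjusted over the list alone. The co-receptor Cd4 was at -2.53 ± 0.69, the chemokine receptor Cxcr6 at -2.07 ± 0.57 and the interleukin receptor chain Il2rb at -1.28 ± 0.36. Cholesterol synthesis genes were next in the kidney, with 19 of 24 lower and a median of -0.31 (fry adjusted p = 0.104). Lss was at -0.36 ± 0.12 and Srebf2 at -0.29 ± 0.10. Targets of the amino acid stress factor ATF4 did not shift together in the kidney, with 19 of 28 higher and a median of 0.26 (fry adjusted p = 0.882; 3 over the list alone). Its 2 called members went the other way: Phgdh, the entry enzyme of serine synthesis, fell by 1.59 ± 0.34 and Slc3a2, the shared heavy chain of amino acid exchangers, by 0.66 ± 0.15. Without kidney 35, 3 kidney lists passed, all lower: T and NK cells and lysosome and autophagy (fry adjusted p = 0.0367 for both) and cholesterol synthesis (0.0439). Without 6 to 11 as well, 4 passed: translation and mTORC1 components (0.0094), cholesterol synthesis (0.0118), and lysosome and autophagy and T and NK cells (both 0.0139). None of these held with an estimated correlation (camera adjusted p = 0.322 to 0.383). In the 2-month liver T and NK cell genes were lower in 23 of 28 cases (median -1.17; Cd247 at -5.08 ± 1.55 and Il2rb at -1.65 ± 0.56). MHC class II genes were lower in 11 of 11 (median -0.79; H2-DMb2 at -2.24 ± 0.69) and ATF4 targets in 19 of 26 (median -0.25; Asns at -2.21 ± 1.01). Each list had a fry adjusted p of 0.0986 (0.229 with an estimated correlation) and no member called over all genes. Adjusted over the list alone, 4, 1 and 1 of them passed.

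At 22 months no gene differed between rapamycin and control with edgeR in either tissue, in both sexes together, in males or in females. Age was uneven in the males: controls 16 and 17 were 20.5 months old, and all rapamycin males were 22 months old. Without 16 and 17, or with age as a covariate, edgeR called 2 genes in male livers and 0 in male kidneys. In the liver 743 genes had an unadjusted p under 0.05 in both sexes, fewer than the 774 that chance gives, with 859 in males and 514 in females; DESeq2 called 1, 9 and 3. In the kidney the numbers were 555, 181 and 800, and DESeq2 called 7, 11 and 10. The liver genes with the smallest p were Aldh3a2, a fatty aldehyde dehydrogenase (-0.64 ± 0.15), Slc16a7 (-0.62 ± 0.15), Rab30 (-0.97 ± 0.24), Cxxc5 (0.43 ± 0.11) and the bile acid transporter Slc10a2 (-1.11 ± 0.30), all with an edgeR adjusted p of 0.885. In the males' liver Nt5e, an enzyme that makes adenosine, came closest (-1.53 ± 0.29, edgeR adjusted p = 0.0575), followed by Tcn2 (-0.81 ± 0.18) and Sh3bgrl2 (-0.67 ± 0.15). In the females' liver the first were Nr1d2, a clock repressor (-1.54 ± 0.40), Cnp (0.81 ± 0.22) and Serpina9 (7.83 ± 2.11). The kidney genes with the smallest p were Mkrn1 (-0.49 ± 0.13), Cdsn (1.99 ± 0.54), Mplkip (-0.47 ± 0.13) and Ntrk3 (2.05 ± 0.57). Genes of fatty acid oxidation under PPAR alpha were lower in 29 of 30 cases in the 22-month rapamycin livers, with a median of -0.26 (fry adjusted p = 0.0516; 0.0827 with an estimated correlation); Angptl4 was at -1.27 ± 0.38 and Cpt1a, the gate of mitochondrial fat import, at -0.44 ± 0.15.

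At 28 months no gene passed with edgeR in any comparison of the 12 groups either. Ages do not overlap in the males, at 28.8 to 29.2 months in controls and 27.6 to 28.4 with rapamycin. With age as a covariate edgeR called 92 genes in male kidneys, 89 of them higher, and 1 in both sexes. That fit kept kidney 35 and its lung transcripts and was not run without it. Without the covariate, edgeR called 0 male kidney genes when kidney 35 was left out. In the liver 681 genes had an unadjusted p under 0.05 in both sexes, 481 in males and 687 in females, and DESeq2 called 0, 2 and 0. The genes with the smallest p were Wfdc17 (-1.31 ± 0.33), the red cell anion exchanger Slc4a1 (-5.11 ± 1.29), Cd24a (-2.62 ± 0.68), the complement factor properdin gene Cfp (-0.93 ± 0.25) and the basement membrane gene Nid1 (0.74 ± 0.21). Single-sex liver values were 3.03 ± 0.76 for Ptgfrn, 1.64 ± 0.44 for Uggt2 and 1.78 ± 0.49 for Ikbip in males, and -0.62 ± 0.15 for Usp39, -0.71 ± 0.17 for Fbxo33 and -0.90 ± 0.22 for Slc46a3 in females. In the kidney 737, 1213 and 467 genes had an unadjusted p under 0.05, and DESeq2 called 5, 85 and 28. Of the 85 calls in males 81 were higher, with kidney 35 kept. Ager and Hopx, both made in alveolar cells, and Akap5 led the male and the joint comparison (7.48 ± 1.69, 6.42 ± 1.34 and 5.82 ± 1.31 in males), and kidney 35 set those values: without it Ager was at -0.68 and Akap5 at -0.21 in males. Leaving out 18, 19, 34 or 36 instead gave 49, 95, 25 or 29 male kidney genes. Stmn2 (2.55 ± 0.66) and Fcmr (-2.64 ± 0.71) followed in both sexes. In females the smallest p values belonged to the lymphocyte factor Ikzf1 (-1.90 ± 0.48), Osbpl10 (0.87 ± 0.23) and Cd180 (-2.29 ± 0.61), a B cell surface protein.

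The change of the rapamycin response with age was tested directly. In the kidney 11 genes had a response at the later ages that differed from that at 2 months, and 8 of them could be named by the fixed rule. Uap1l1 was at -1.73 ± 0.18 at 2 months, -0.12 ± 0.16 at 22 months and -0.00 ± 0.16 at 28 months (edgeR adjusted p = 0.000124). Tbxas1, the thromboxane synthase gene, was at -1.92 ± 0.23, 0.22 ± 0.19 and 0.03 ± 0.19 (edgeR adjusted p = 0.00013). Rnase4 was at -3.34 ± 0.48, -0.17 ± 0.38 and 0.28 ± 0.38, Ang at -4.0 ± 0.58, -0.27 ± 0.42 and 0.04 ± 0.42, and Tmem178b at -2.12 ± 0.43, 0.88 ± 0.35 and -0.08 ± 0.34. Acss1, a mitochondrial enzyme that activates acetate, was at -1.05 ± 0.17, 0.02 ± 0.15 and -0.01 ± 0.15, Mlph at -1.03 ± 0.19, 0.30 ± 0.16 and 0.06 ± 0.16, and Cyp20a1 at -0.45 ± 0.10, -0.02 ± 0.08 and 0.24 ± 0.08. Uap1l1 and Tbxas1 passed in all 48 fits that left out 1 kidney, and the count ranged from 2 (without 43) to 40 (without 35). The liver gave no such gene with edgeR (913 at an unadjusted p under 0.05, 20 with DESeq2).

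Liver and kidney were also fitted together over the 15224 shared genes that passed the count filter. At 2 months 18 genes responded differently in the tissues, 8 with a higher value in the liver response and 10 with a lower one; limma voom called 3. With the shared number as a block 6 were called, Rnase4, Ang, Ugt2b34, Gpat3, Ttpa and Hspb1. Rnase4 (liver 0.32 ± 0.24, kidney -3.34 ± 0.48), Ang (0.44 ± 0.30 and -4.0 ± 0.58), and Ugt2b34 (0.13 ± 0.16 and -2.41 ± 0.39) fell in the kidney and were not called in the liver. So did Gpat3, an enzyme of triglyceride synthesis (0.52 ± 0.22 and -1.17 ± 0.24), and Ttpa, the vitamin E transfer protein (0.34 ± 0.16 and -1.45 ± 0.31). Hspb1 had the opposite arrangement, at -2.63 ± 0.45 in the liver and 0.44 ± 0.43 in the kidney. For Rgs6 and Ano9 the difference of liver minus kidney was -5.72 ± 1.14 and -4.86 ± 1.05, and neither passed the count filter in the liver alone. Of the 74 genes called in the 2-month kidney, 63 were tested in the liver, where 45 had the same direction and 0 were called; of the 15 liver genes, 12 were tested in the kidney, 8 had the same direction and 0 were called. No gene differed between tissues at 22 months (777 at an unadjusted p under 0.05; 0 with limma voom). At 28 months 5 did: Bmpr1b, a receptor of bone morphogenetic proteins (liver minus kidney 6.27 ± 1.17), Slc4a1 (-5.21 ± 1.11), Zfp13 (3.78 ± 0.81), Trim16 (-4.93 ± 1.06) and 1810046K07Rik (4.71 ± 1.0), the last named outside the rule after its value was seen. With the shared number as a block edgeR called none of these 5, and limma voom gave 1 call, as did edgeR without a count filter. Leaving out 1 number at a time, edgeR called 0 (without 6, 29 or 18) to 4 genes at 28 months.

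Ageing in control livers, 28 against 2 months, changed 451 genes, 288 higher and 163 lower. Of the 10 lists that passed fry, only B and plasma cells held with an estimated correlation, and the camera adjusted p of each other is given with it. The B and plasma cell list rose, with 10 of 21 members called higher (17 when adjusted over the list alone; fry adjusted p = 4.58e-07, and 0.000992 with an estimated correlation), led by the antibody genes Igkc (4.12 ± 0.58) and Ighm (3.30 ± 0.58) and by Jchain (3.64 ± 0.64). Acute phase genes were higher in 33 of 34 cases with 13 called (20 over the list alone; camera 0.144): Saa2 rose by 5.79 ± 1.22, Lcn2 by 4.77 ± 1.01, Hp by 1.55 ± 0.33 and Apcs by 1.98 ± 0.40. Senescence and DNA damage genes (5 of 26 called higher and 1 lower, 8 over the list alone; camera 0.144; Bax 0.73 ± 0.15, Eda2r 3.87 ± 0.86) rose as well. So did interferon response genes (6 of 47, 19 over the list alone; camera 0.281; Psmb8 1.44 ± 0.30, Oasl1 1.41 ± 0.30). Macrophage genes (3 of 30, 12 over the list alone; camera 0.265; Mpeg1 1.76 ± 0.34) and neutrophil genes (4 of 13, 5 over the list alone; camera 0.265; S100a9 3.97 ± 0.93, Prtn3 5.97 ± 1.5) also rose. Female-biased genes under growth hormone control rose (6 of 44 called higher and 1 lower, 12 over the list alone; camera 0.197; Ntrk2 3.79 ± 0.70, Cd36 1.74 ± 0.38). Male-biased ones fell (6 of 37 called lower and 1 higher, 15 over the list alone; camera 0.197; Slco1a1 -2.85 ± 0.45, Cyp2d9 -2.29 ± 0.39). PPAR alpha targets were lower as a list by fry alone (24 of 30 lower, 0 called, 0 over the list alone; camera 0.265). Bile acid genes fell (3 of 22 called lower and 1 higher, 8 over the list alone; camera 0.265; Abcc2 -0.92 ± 0.20, Abcb4 -0.57 ± 0.15, with Slc10a2 at 2.13 ± 0.35). Among other genes with large changes, Dntt, which diversifies antigen receptors, rose by 4.26 ± 0.61, Wfdc15b by 5.82 ± 0.74, Dmrta1 by 4.77 ± 0.54, Hsf2bp by 4.50 ± 0.59 and Sult2a7, from a family that can share reads, by 4.41 ± 0.84. Hsd3b2 fell by 1.98 ± 0.24, Hsd3b5 by 3.32 ± 0.85, and Cyp3a11 by 2.28 ± 0.53. The collagen gene Col1a2 (-1.63 ± 0.40), Cdh1 (-3.43 ± 0.76), Nrep (-1.82 ± 0.41) and Ptgfrn (-2.11 ± 0.46) fell too. The 28-month males rest on 2 libraries: without 29 the count was 96, and without 46, 40 or 42 it was 274, 297 or 294.

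In control kidneys ageing changed 636 genes, 570 of them higher and 66 lower. All 11 MHC class II genes tested rose (11 when adjusted over the list alone; fry adjusted p = 3.44e-05, 0.00498 with an estimated correlation), with Cd74 at 2.62 ± 0.35, H2-Aa at 2.35 ± 0.31 and H2-Ab1 at 2.40 ± 0.34. B and plasma cell genes rose in 12 of 14 cases (12 over the list alone), with Jchain, the joining chain of secreted antibodies, at 7.81 ± 1.14, the B cell factor Pou2af1 at 5.18 ± 0.84 and the CD20 gene Ms4a1 at 5.01 ± 0.88. Macrophage genes rose in 20 of 28 cases (23 over the list alone; C1qb 2.38 ± 0.40, Itgam 2.89 ± 0.48) and T and NK cell genes in 12 of 30 (18 over the list alone; Ccl5 3.29 ± 0.62, Cd2 3.97 ± 0.90). These 4 lists held with an estimated correlation; without kidney 35, whose removal was chosen after its values were seen, only MHC class II still did (camera adjusted p = 0.0191, the others 0.0504 to 0.0714). The next 5 lists passed fry but not camera with an estimated correlation (adjusted p = 0.1 for senescence, 0.211 to 0.285 for the others). Tubule injury genes (7 of 28 called, 19 over the list alone; camera 0.211; Vcam1 1.83 ± 0.32, Lcn2 3.16 ± 0.80) rose, as did acute phase genes (11 of 31, 21 over the list alone; camera 0.211; Cxcl13 5.05 ± 0.96, Socs3 3.51 ± 0.68). Interferon genes (10 of 46, 28 over the list alone; camera 0.285; Tap1 1.56 ± 0.33) and senescence genes (5 of 25, 8 over the list alone; Cdkn2a 5.32 ± 1.43, Gdf15 1.47 ± 0.35) rose too. Heat shock genes fell as a list (18 of 20 lower, 9 over the list alone, camera 0.262), although its 1 called member, Hspb8, rose by 1.47 ± 0.37. The protease inhibitor Slpi (5.10 ± 1.08), Ccl8 (5.37 ± 1.26), and Cxcr5 (4.81 ± 1.09) were among those that rose most, with Cd22 (4.70 ± 0.93), Pax5 (4.67 ± 1.17), Fcrla (4.35 ± 0.92) and Cnpy1 (4.43 ± 0.83). Those that fell most were Rnf24 (-1.86 ± 0.56), the fatty acid hydroxylases Cyp4a14 (-1.85 ± 0.30) and Cyp4a10 (-1.26 ± 0.37), and Mogat2 (-1.84 ± 0.46). Next came Ano3 (-1.58 ± 0.47), Gadd45g (-1.29 ± 0.34), Car14 (-1.21 ± 0.36), Slc25a25 (-1.19 ± 0.31) and Aplnr (-1.12 ± 0.31). The count was 1067 without kidney 35, 270 without 20, 991 without 21, and 416, 403, 407 and 418 without 46, 47, 41 and 42.

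Sex separated control livers at 1324 genes, 687 higher in males and 637 higher in females, averaged over the 3 ages. Genes under the sex-specific pattern of growth hormone secretion led: 32 of 37 male-biased genes were called higher in males (34 in either direction over the list alone), with Cyp2d9 at 6.12 ± 0.34, the complement gene C6 at 4.67 ± 0.27 and Gstp1 at 3.10 ± 0.20. Of the female-biased genes, 39 of 44 were called higher in females (43 over the list alone), with Cyp3a44 at -8.99 ± 0.59 and the transcriptional regulator Trim24 at -1.94 ± 0.15. Stellate cell and fibroblast genes were higher in females (11 of 19 called, 12 over the list alone; Colec11 -0.79 ± 0.13, Pdgfra -0.99 ± 0.21). These 3 lists held with an estimated correlation and 11 others that passed fry did not. Male livers also had far more Mup7 (11.76 ± 1.03), Cyp4a12a (10.71 ± 0.79) and Hsd3b5 (8.95 ± 0.77), and female livers more A1bg (-11.89 ± 1.47) and Sult2a2 (-12.11 ± 0.80). The Mup, Cyp4a, Cyp3a and Sult2a families hold near-identical copies that can share reads. The Y-linked Eif2s3y, Kdm5d and Uty followed the labels. Without the 28-month male control 21 the liver count was 759. In control kidneys 2474 genes differed, 1188 higher in males and 1286 higher in females. Of the androgen-responsive list, 23 of 26 members were called higher in males (24 in either direction over the list alone; fry adjusted p = 3.41e-09, 0.00384 with an estimated correlation). The anion transporter Slco1a1 was higher by 11.38 ± 0.71, Cyp2j13 by 9.26 ± 0.65, the amino acid transporter Slc7a13 by 9.0 ± 0.64 and Adh1 by 2.14 ± 0.19. Collecting duct genes (12 of 22 called, 16 over the list alone; camera 0.167; Scnn1g -0.81 ± 0.17, Atp6v0d2 -0.67 ± 0.13) were higher in females. So were podocyte genes (11 of 17 called, 15 over the list alone; Wt1 -1.12 ± 0.21, Podxl -0.74 ± 0.14). Neither list held with an estimated correlation (camera adjusted p = 0.167 for both). Ugt1a2 (-10.03 ± 0.44), the growth factor Igf2 (-5.99 ± 0.57), Cyp4a14 (-5.80 ± 0.30), Tmprss6 (-5.60 ± 0.55), Akr1c20 (-4.81 ± 0.38) and Slc7a12 (-4.42 ± 0.57) were higher in female kidneys. Ugt2b37 (7.51 ± 0.64), Cyp7b1 (6.28 ± 0.58), Pzp (5.86 ± 0.59) and Col6a6 (5.29 ± 0.52) were higher in male kidneys.

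To place the rapamycin groups on the axis of ageing, each library received a score: the mean standardized log2 CPM of genes that rose with age minus that of genes that fell, with the genes taken from controls of the other sex. The liver score was lower with rapamycin at each age, by 0.27, 0.53 and 0.36 SD units in the mean of both sexes at 2, 22 and 28 months, but none of these differences passed an exact permutation test (p = 0.307, 0.0926 and 0.26; Benjamini-Hochberg adjusted over 6 tests 0.614, 0.556 and 0.614). At 22 months male livers scored 0.956 ± 0.876 with control diet (SD, n = 4) and 0.179 ± 0.381 with rapamycin (n = 4), and female livers 0.394 ± 0.561 (n = 5) and 0.111 ± 0.396 (n = 3). Male controls 16 and 17 were 20.5 months old and the rapamycin males 22 months. Single libraries moved these differences: the 2-month one was -0.13 without liver 48, the 22-month one -0.31 without 30 and the 28-month one -0.10 without 29. Kidney differences were -0.16, 0.11 and 0.07 (exact permutation p = 0.631, 0.758 and 0.865). The male kidney scores rested on 10 rising genes and 1 falling gene, which weighed as much as the mean of the 10. They place male kidneys on the axis of ageing only poorly. Without kidneys 6 to 11, a fit chosen after the data were seen, the male score rested on 4 rising genes and no falling one, and the differences were 0.54, 0.48 and 0.52 (exact permutation p = 0.00714, 0.0757 and 0.115), and without 35 as well 0.22, 0.38 and 0.66 (0.447, 0.309 and 0.149). With the ageing genes taken from 22-month controls, the liver difference at 22 months was -0.62 (exact permutation p = 0.00485), that at 28 months was -0.08 and that at 2 months turned to 0.37. At 22 months it was -0.23 with 200 genes each way and -0.40 with genes of mean log2 CPM 3 or more (exact permutation p = 0.273 and 0.21).

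**Figure D4:**
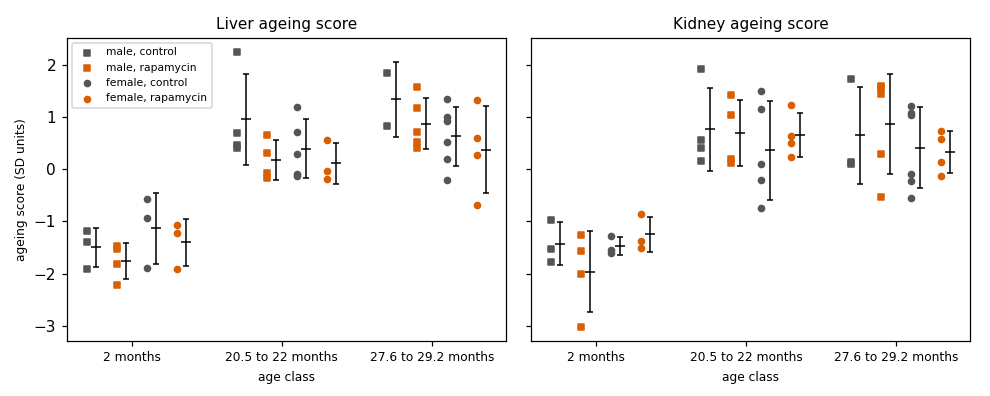
Ageing score of each library (vertical axis, SD units) in liver and kidney by age class (horizontal axis), with squares for males, circles for females, grey for control and orange for rapamycin; bars beside the points give mean ± SD. The 2-month groups all have means at or below -1.13 and the older groups means at or above 0.111.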

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

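The test of lung markers that other kidneys lack and the comparison of T and NK cell genes in the livers were chosen only after the results were seen, as were the fits without kidney 35 and without kidneys 6 to 11.

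Some libraries lay far from the others of their group by a Dixon test on 78 groups, which by chance alone marks about 1 in 20 groups; it marked 7 values. In the 22-month female control kidney of number 10, the fat hormone Adipoq was at 67.9 CPM (next 1.89) and Scgb1a1 at 0.0549 CPM, the other 4 being at 0. Adipoq was higher still in kidneys 8 and 12 (370 and 216 CPM), which the test did not mark within their groups. In the 28-month male rapamycin kidney of number 35, Scgb1a1 was at 51947 CPM and Sftpc at 17499 CPM. The 22-month male control liver of number 30 had an ageing score of 2.26 (next 0.699). Total gene counts were 13.6 M in the 22-month female control kidney of number 1 (next 16.9) and 52.8 M in the 22-month male rapamycin liver of number 14. Differences between groups were the 11 kidney genes whose rapamycin response changed with age, and the 18 genes at 2 months and 5 at 28 months whose response differed between liver and kidney.

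Kidney 35 carried abundant lung transcripts. Of 18 lung markers in a list without the genes first seen, 12 (66.7%) were at least 10 times the highest other kidney, under the 75% set beforehand for lung tissue. Among the 9 markers below 1 CPM in every other kidney, 8 did so (88.9%), a test chosen after the first. Kap and Umod were far below every other male kidney, so lung RNA could make up much of this library. No biological explanation was tested, and kidney 35 was kept in the values of the report.

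Kidneys 6 to 11 resembled the liver of the next number. Time of day shared by neighbouring animals is argued against, because with 100 genes unrelated to the clock all 6 still matched the next liver best. A shift of the kidney labels by 1 may explain it, but with the next 200 genes by rank only 2 of 6 matched the next liver best, between the bounds set beforehand, so it stays open. Kidneys 11 and 12, the closest pair, both matched liver 12 best (r = 0.66 and 0.619; 0.105 for kidney 11 with liver 11), so 1 animal could stand behind both of these 28-month control females. No library was given another label.

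The 2-month kidney response was weighed against fat in the tissue pieces and against genotypes shared within litters. With a fat covariate 70 of 74 calls (94.6%) remained, but the covariate could move little: the fat list differed by only -0.054 in the mean of both sexes (exact permutation p = 0.971), lower by 1.71 in males and higher by 1.61 in females. For the 104 male genes fat was not tested. Fat moved opposite ways in the sexes. The 74 genes, signed by their mean change, moved the same way in both (1.82 log2 CPM in males, 1.18 in females). That argues against fat as the only cause of the 74, although they were chosen on the mean of both sexes. The mean liver to kidney correlation of 63 of these genes was at percentile 85.8 of random sets, between the bounds set beforehand, so shared litter genotypes could contribute and cannot be told apart from rapamycin here, since the labels give no litter.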

How the results depend on the processing

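The fits without kidney 35, without kidneys 6 to 11 or without both, the sum of kidneys 11 and 12 and the fat covariate were chosen after the data were seen; all others were planned. The cause of a change was not tested unless the alternative itself removes libraries. RLE factors and summing kidneys 11 and 12 (69 calls for the 2-month kidney) moved no count of calls past 1.5 times. Depth limits genes near the floor, and groups of 2 to 6 libraries limit small changes.

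With DESeq2 the kidney gave 154, 15 and 312 genes at 2 months (both sexes, females, males), 7, 10 and 11 at 22 months, 5, 28 and 85 at 28 months and 54 for age by rapamycin. The liver gave 62 and 9 at 2 months (both, females), 1, 3 and 9 at 22 months, 2 in males at 28 months, 20 for age by rapamycin, 2 for sex by rapamycin and 803 for ageing. With age as a covariate the kidney gave 4 for age by rapamycin, 1 and 92 at 28 months (both, males) and 1584 for sex, and the liver 688 for ageing, 2 in 22-month males, 1 in 2-month females and 758 for sex. Fits of 2 groups gave 30 (2-month female kidney), 3 (22-month female liver) and 1 (2-month male liver), and fits of 4 groups 403 and 8 (2-month kidney and liver). Without the 20.5-month males, which were all controls, the 22-month male liver gave 2. With a preset correlation, camera passed 12, 15 and 15 kidney lists and 19, 11 and 14 liver lists at 2, 22 and 28 months, where fry passed 0.

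With 22-month in place of 28-month controls, ageing gave 34 kidney and 227 liver genes, Epb42 went to 0.00, and Lyz2 (-0.0482) and Slc4a1 (-2.48) reversed. With ageing defined at 22 months the liver score difference was -0.616 at 22 months (exact permutation p = 0.00485) and reversed to 0.374 at 2 months. With 200 genes each way the differences at 2, 22 and 28 months were -0.228, -0.229 and -0.405 in the liver and -0.0117, 0.0131 and 0.0148 in the kidney. The 2-month kidney score difference reversed to 0.0207 with genes of mean log2 CPM 3 or more (0.306 at 28 months), to 0.536 without kidneys 6 to 11 (exact permutation p = 0.00714; 0.483 and 0.520 at 22 and 28 months; males scored on 4 rising genes and no falling one) and to 0.217 without 6 to 11 and 35.

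Without kidney 35 the kidney gave 232, 4 and 465 genes at 2 months (both, females, males), 40 for age by rapamycin, 1067 for ageing, 1 for sex by rapamycin and 3 lists at 2 months. Without 6 to 11 it gave 4 for age by rapamycin and 2 lists. Without all 7 it gave 325, 2 and 559 genes, 26 for age by rapamycin, 977 for ageing, 1 for sex by rapamycin and 4 lists. At 28 months Ager and Akap5 reversed to -0.0612 and -0.0452 in both sexes and -0.682 and -0.215 in males without 35, and to -0.0253, -0.0605, -0.687 and -0.218 without all 7.

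For the tissue difference at 2 and 28 months, voom gave 3 and 1 genes, no filter 1 at 28 months, and the fit without 6 to 11 and 35 gave 29 and 2. With the shared number as a block there were 6 and 0. The plan left pairing by number out of the joint fit. Residuals of liver and kidney with the same number correlated at a median r of 0.0935 (-0.0772 to 0.261, 19 of 46 above 0.1), but 5 of 6 kidneys held out when 100 matching genes were chosen correlated best with the liver of their own number, so calls lost with the block are not secure.

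Leaving out 1 library at a time from the groups each result compares gave these ranges; kidney 35, outside the 2-month and ageing contrasts, moved those further as given above. Kidney counts were 32 to 96, 0 to 2 and 24 to 359 at 2 months (both, females, males), 0 to 95 in 28-month males, 2 to 40 for age by rapamycin, 0 to 1 for sex by rapamycin, 270 to 991 for ageing and, leaving out any kidney, 0 to 3 lists at 2 months. Kidney score differences were -0.275 to 0.0201, -0.0307 to 0.3004 and -0.0721 to 0.336 at 2, 22 and 28 months. Liver counts were 5 to 19, 0 to 2 and 10 to 21 at 2 months, 0 to 1 in 22-month males, 0 to 1 for age by rapamycin, 96 to 532 for ageing, 759 to 1425 for sex and 0 to 1 lists at 22 and at 28 months. Liver score differences were -0.460 to -0.131 at 2 months, -0.615 to -0.104 at 28 months and -0.642 (without 7, exact permutation p = 0.0469) to -0.314 at 22 months, and the tissue difference 4 to 19 at 2 and 0 to 4 at 28 months. Without the male control liver 41, Awat2 reversed to 0.442 for ageing (lowest -3.67) and to 0.983 for rapamycin in 2-month males (lowest -6.43), where Far1 (-4.72 to 0.47) and Nupr1 (-7.55 to 0.365) reversed too. The highest values of Ager and Akap5 at 28 months, with 35 kept, were 4.24 and 3.13 in both sexes and 7.92 and 6.14 in males.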

Other observations

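The tests of T and NK cell genes in the livers and of lists by permutation were chosen only after the results were seen. Ageing changed some of the same genes in both tissues. Of 12779 genes in both fits, 55 rose with age in liver and kidney (233 and 524 called; 9.55 expected if the tissues were independent, which livers and kidneys of the same numbers may not be), among them the B cell receptor gene Cd79a (3.05 ± 0.67 in liver, 4.31 ± 0.84 in kidney), the leukocyte genes Cd52 (2.49 ± 0.43 and 2.73 ± 0.44) and Coro1a (1.54 ± 0.30 and 2.45 ± 0.41), and Plek (2.23 ± 0.44 and 2.33 ± 0.42). Only 5 fell in both (0.711 expected): Atxn1, Ide, the insulin-degrading enzyme gene, Larp4b, Scfd2 and the basement membrane collagen Col4a2 (-1.12 ± 0.25 and -0.49 ± 0.14), and 2 went opposite ways. For sex, 142 genes were higher in males in both tissues (49.6 expected), such as Slco1a1 and Cyp7b1, 117 higher in females (46.5 expected), such as the prolactin receptor Prlr (-1.97 ± 0.21 and -3.66 ± 0.52), and 72 went opposite ways.

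The male-biased liver gene Slco1a1 was at 127 ± 111 CPM in 2-month control females (SD, n = 3) and 3.31 ± 1.33 and 4.07 ± 1.37 CPM at 22 and 28 months (n = 5 and 6), against 662 ± 136, 450 ± 264 and 396 ± 233 CPM in males (n = 3, 4 and 2). Whether the sexes differ in their change with age was not tested.

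The 2-month response could last into old age. The 74 kidney genes, signed by their 2-month change, differed by 1.5 log2 CPM at 2 months, but by -0.00784 at 22 months (exact permutation p = 0.898, interval -0.117 to 0.102) and 0.159 at 28 months (p = 0.19, interval -0.0569 to 0.375). The 15 liver genes differed by 1.80 at 2 months, -0.00611 at 22 months (exact permutation p = 0.949) and 0.178 at 28 months (p = 0.0782, interval -0.017 to 0.374). All 4 intervals stay below 0.5 of the 2-month difference, which argues against persistence at 0.5 of these estimates and leaves smaller effects open. The 2-month differences come from the libraries that chose the genes, so they are likely too large. Their own intervals were 0.581 to 2.42 in the kidney and 0.676 to 2.93 in the liver. Each interval spans, on both sides of the difference, the absolute size that a share of 0.05 of all treatment arrangements exceeded. At 2 months the arrangements mix groups that differ strongly, which widens the interval. These are therefore not confidence intervals. In the 2-month livers 63 of the kidney genes differed by 0.186 in the same direction (exact permutation p = 0.0486, adjusted over 5 tests 0.196; interval 0.00328 to 0.369). That met both bounds written beforehand, a p under 0.05 and an interval below 0.5 of the kidney difference; the second was taken to decide, a choice made after the value was seen, so a weak shared response stays open.

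Rapamycin may lower the content of T and NK cells, or of immune cells more widely, in young tissue. In the 2-month kidney the mean log2 CPM of this list was lower by 0.825 with rapamycin (exact permutation p = 0.00143, adjusted over the lists 0.0195), at -1.11 ± 0.19 against -2.16 ± 0.15 in males (SD, n = 3 and 4) and -1.25 ± 0.21 against -1.85 ± 0.22 in females (n = 3 and 3), without overlap in either sex. The livers, which carry the same numbers as the kidneys and are no independent check, gave -0.602 (exact permutation p = 0.0143, adjusted 0.135). Liver means were -1.66 ± 0.14 against -2.52 ± 0.17 in males (SD, n = 3 and 4). In female livers they were -1.58 ± 0.35 against -1.92 ± 0.49 (n = 3 and 3), and the treatments overlapped. Group means of the T and NK cell list were negative on the log2 CPM scale in both tissues, so low counts limit these values. Other lists of immune genes were lower too: MHC class II (-0.886), B and plasma cells (-0.523) and macrophages (-0.469) in the liver, and B and plasma cells and interferon genes (both -0.532) in the kidney (exact permutation p = 0.00286 to 0.0271, adjusted 0.0586 to 0.149). The 2 kidney differences came mostly from males (-0.960 and -0.881, against -0.105 and -0.184 in females). Interferon genes (-0.348) and neutrophils (-0.284) in the liver did not pass (exact permutation p = 0.0657 and 0.201). In the kidney MHC class II (-0.254), macrophages (-0.229) and neutrophils (0.249) did not either (exact permutation p = 0.0814, 0.163 and 0.274). Some lists other than immune ones were lower too, by p values given here without adjustment over the lists. ATF4 targets (-0.394, exact permutation p = 0.00143) and endothelium (-0.297) were lower in the liver and proximal tubule genes (-0.240) in the kidney (exact permutation p = 0.0214 for both). Cholesterol synthesis (-0.307) and translation and mTORC1 genes (-0.124) were lower in the kidney with the same p of 0.00143, the smallest that 700 arrangements allow in this exact test. None of these lists passed fry with all libraries, so this stays a hypothesis.

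Counts were compared with other splits of the same libraries. The splits shuffled single libraries, or numbers for the tissue difference, so they cannot exclude a grouping by litter, which the labels do not give. With at least 21 splits, a real count above every other one excludes random shuffling at the 0.05 level. This held at 2 months for the 15 liver genes in both sexes (highest other 4, 1 of 40 splits as large) and the 74 kidney genes (5, 1 of 40). It also held for sex in liver (1324 against 3, 1 of 24) and kidney (2474 against 643, 1 of 24) and ageing in kidney (636 against 0, 1 of 24). The 18 tissue differences at 2 months passed too (2, 1 of 21), in the fit without a block. With the shared number as a block 6 calls were left, and that fit was not split. Random shuffling is not excluded for the 26 genes in 2-month male livers (758, 3 of 35) or the 104 in male kidneys (381, 2 of 35). Nor is it for the 11 kidney genes of age by rapamycin (532, 2 of 40). Females at 2 months allow only 10 splits, too few for a share under 0.05: 0 in the liver (highest other 1; 10 of 10) and 1 in the kidney (0; 1 of 10). Where the real count was 0, every split was as large. In the liver the highest others were 1 (40 splits), 9 (35) and 0 (40) at 22 months in both sexes, males and females, 3 (40) in 28-month females, 1 (40) for sex by rapamycin and 29 (40) for age by rapamycin. In the kidney they were 0 (40), 1 (35) and 275 (40) at 22 months, 3829, 5551 and 47 (40 each) at 28 months and 1389 (40) for sex by rapamycin, and for the tissue difference at 22 months 1 (21). What the splits calling 3829 and 5551 kidney genes reflect stays open, since none was run without kidney 35. Liver ageing, 28-month male and joint comparisons have a group of 2 and were not split.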
